A study of Schmidtea mediterranea with 60 samples.

How the data were processed

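The samples were 60 libraries of the planarian Schmidtea mediterranea, a freshwater flatworm that regrows its whole body from small fragments, in 2 experiments of 36 tail and 24 whole-body libraries. The labels give each library's tissue, the RNAi, the time and a replicate number, and every group holds 3 libraries. Per the labels' protocols, total RNA was extracted with TRIGene reagent, 400 ng of it went into each library, and the kit was an NEBNext Ultra RNA SMARTER kit for Illumina. RNAi lowers a chosen transcript, in planarians by giving double-stranded RNA (dsRNA) of its sequence, and egfp, which codes for a jellyfish protein, served as the control dsRNA. In the tails each animal group had a pair of dsRNAs, named in the labels as egfp with egfp, opa1 with egfp, or opa1 with drp1, and libraries were taken at 0dpa, 6hpa, 1dpa and 2dpa, days or hours post amputation. Below these are called control tails, opa1 RNAi tails and combined RNAi tails. Whole bodies had egfp, opa1, drp1 or sod2 RNAi and were taken at 1dpa or at a time labelled homo, a label whose meaning is not given in the sources used here. The labels do not say whether the replicates were separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

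The whole-body table holds estimated counts per feature as deposited by the authors, from kallisto by the name of the deposited table, with the version, the index and the build not given in the sources used here. Of its values, 89.8% to 91.5% per library were whole numbers. The tail table holds a signal, values that the authors deposited already scaled between libraries, with the method of scaling not given in the sources used here, and 0 of its non-zero values were whole. The deposited TPM tables, which give each feature's length-scaled share of a library, were used for alternatives only. The tail one holds 27444 features with 0.47 to 0.74 of a library's full TPM. That part was larger with opa1 RNAi than in controls at each time, which moves fold changes on it. There were 36035 features in the tail table and 36034 in the whole-body one, and no per-sample column was left unused. The files do not pair the feature IDs with gene names and no name table was used, so 0 features could be matched to opa1, drp1, sod2 or any of 35 gene lists that had been fixed, and those list tests were not run.

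Whole-body counts were rounded to whole numbers and tested with edgeR 4.0.16, using TMM scaling, its filter for low counts and quasi-likelihood tests over all 24 libraries with 8 group means, which left 22889 features. The design planned the same test for the tails. Since the tail values are not counts, limma 3.58.1 with a mean-dependent prior was used instead, on log2 of the value plus a pseudocount of 1, for the 20681 features at 10 or more in at least 3 libraries, over all 36 libraries and 12 group means. Tail fold changes are therefore on the log2(value + 1) scale, which understates the change of low features. All p-values were adjusted by the Benjamini-Hochberg method within a comparison, and a feature is called when its adjusted p is under 0.05. There were 18 tail and 12 whole-body comparisons: each RNAi against its control at each time, combined against opa1 RNAi tails, opa1 against drp1 RNAi whole bodies, control times against each other, and the change of an RNAi effect with time, tested as an interaction. SE is the standard error of a log2 fold change, and SD is over the 3 libraries of a group.

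Named features were chosen by a rule written, like the tests and most alternatives, before the data were examined. It applies to opa1 RNAi against control tails, combined against opa1 RNAi tails, each whole-body RNAi against its control, and later against first times in controls. From each it takes the 2 largest rises and 2 largest falls by log2 fold change among called features with a mean log2 level of at least 1 and every library of one group above every library of the other, a separation that chance gives in 10% of features with 3 libraries against 3. Its parts on the targeted genes and on members of gene lists needed gene names and could not be used. Features chosen after their values were seen are said to be so, and features with near-identical copies, between which reads can be split, are uncertain. Groups of features were formed from called features changed over 2-fold, the 200 with the smallest p where there were more and at least 5, in one experiment and tested in the other, which shares no libraries with it, with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment was over the 252 tests in tails and the 168 tests in the whole body. Of these, 103 and 105 were called with the preset correlation and 36 and 56 with an estimated one, all of the latter in the same direction. For comparisons that share control libraries, 10 simulated pairs of unchanged groups against shared controls gave the overlap and covariance that sharing adds with no effect. Such groups are seldom called, so their overlap sets no bound on what sharing adds to calls of real effects.

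Library totals of the whole-body counts were 10610000 to 14330000, and the deposited scaled values of the tail libraries summed to 8345000 to 14470000, which is not a read depth. Both fits were tested on simulated data. In the simulated whole-body comparison of opa1 RNAi with control at homo, over 22082 features, 65.7% of 2-fold and 83.8% of 4-fold changes were called, and 3.27% of the calls were false. In the simulated comparison of opa1 RNAi with control tails at 1dpa, over 19992 features, 50.5% and 79.6% were called, and 6.57% of the calls were false. Unchanged simulated comparisons gave 0 calls with either tool.

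Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low values, TPM on a log2 scale with pseudocounts of 1 and 0.1, a fold threshold, fits of only the groups compared, the replicate number as a block, and each library left out in turn. Added after the data were seen were TMM rescaling of the tail values, a pseudocount of 0.1 on them, a fit without the 6hpa libraries and a fit without the most abundant tail feature. R 4.3.3 was used for tests, and figures were drawn with matplotlib 3.10.9 in python 3.11.15.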

Results

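RNA was sequenced from planarian tails and whole bodies after RNAi against genes of the mitochondria, and the series title places the work in whole-body regeneration. Opa1 codes for a GTPase that fuses the inner mitochondrial membrane, drp1 for a dynamin-related GTPase that divides mitochondria, and sod2 for the manganese superoxide dismutase of mitochondria. There were 36 tail libraries in 12 groups and 24 whole-body libraries in 8 groups, with 3 libraries in each. Whole-body libraries summed to 10610000 to 14330000 estimated counts, and 27784 to 30179 features were above 0 in a library. Tail values, already scaled by the authors, summed to 8345000 to 14470000 per library, with 22365 to 28543 features above 0. Pairs of libraries of one group correlated at r = 0.946 to 0.977 in tails and 0.976 to 0.985 in whole bodies. These correlations are across features, which are not independent replicates. No 2 libraries of one group were identical over all features, and whole-body replicates differed by more than counting noise, with a chi-square per degree of freedom of 2.17 to 9.36.

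The 6hpa tail libraries stood apart from all other tail libraries on the first principal component, which held 40.5% of the variance, against 9.55% on the second. In whole bodies the first component, with 30.9%, set the opa1 and drp1 RNAi libraries at homo apart from all others, and the second held 9.36%.

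**Figure D1:**
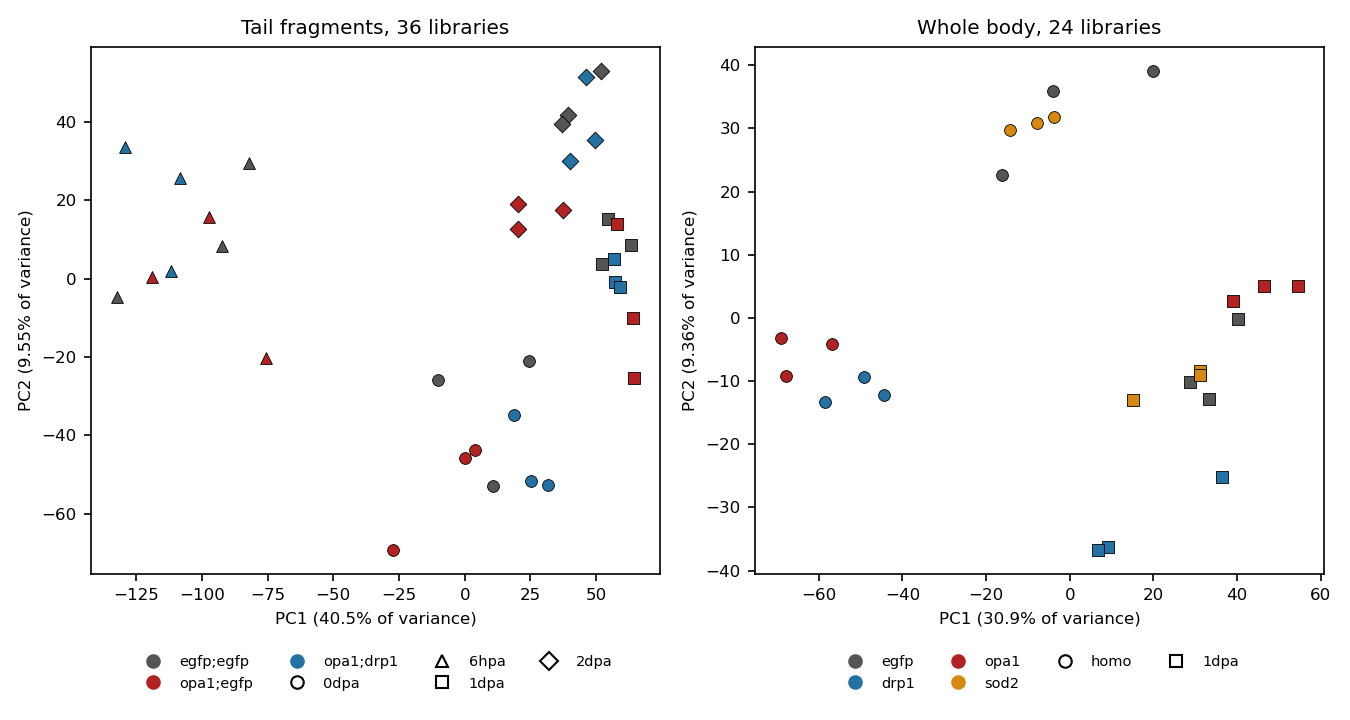
Principal components of log2 values in tails and whole bodies, with the first component on the x axis and the second on the y axis and the percent of variance in each label. Each point is a library, colours give the RNAi and shapes the time. Tail libraries of 6hpa and whole-body libraries of opa1 and drp1 RNAi at homo lie apart on the first component.

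The transcripts of opa1, drp1 and sod2 could not be looked up, since the files do not pair feature IDs with names, so no level of a targeted gene is given here. Some features did fall wherever one dsRNA had been given. They were chosen after their values were seen and are not named as targets. SMED30027152 was lower in all 10 comparisons of drp1 dsRNA present with absent, opa1 against drp1 RNAi left aside, by 9.22- to 16.2-fold, with a highest adjusted p of 7.5e-16 by limma or edgeR. In whole bodies it stood at 104 ± 9.32 CPM in homo controls (SD, n = 3) and at 6.46 ± 0.458 CPM with drp1 RNAi. SMED30010319 was lower in all 10 such comparisons of opa1 dsRNA, by 2.72- to 8.27-fold, with a highest adjusted p of 0.00038 by limma or edgeR. It fell from 35.6 ± 4 to 4.3 ± 0.789 CPM at homo (SD, n = 3), and drp1 RNAi also lowered it there, by a log2 fold change of -0.43 (edgeR, adjusted p = 0.00376). SMED30014993 rose in these 10 opa1 comparisons, by 2.96- to 5.68-fold, with a highest adjusted p of 0.00992 by limma or edgeR. With sod2 RNAi, SMED30002662 fell from 91 ± 7.98 to 1.54 ± 0.181 CPM at homo and from 92.5 ± 3.79 to 2.02 ± 0.498 CPM at 1dpa (SD, n = 3).

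**Figure D2:**
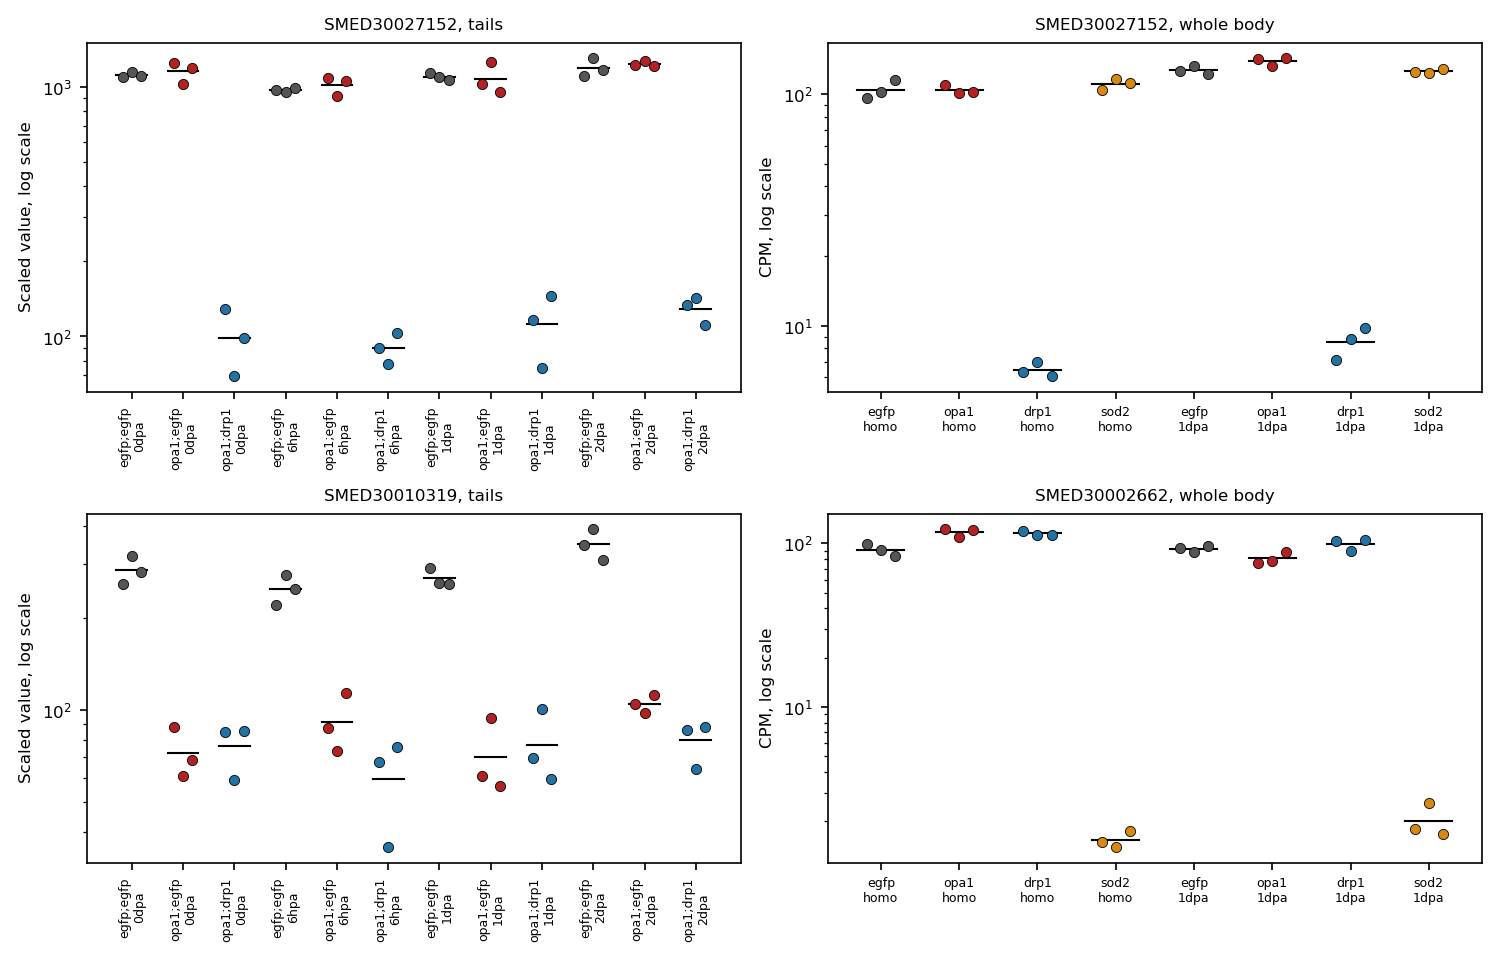
Levels of SMED30027152 in tails and whole bodies, SMED30010319 in tails and SMED30002662 in whole bodies, on log axes in the authors' scaled values or CPM. Points are libraries and lines are group means of 3 libraries. SMED30027152 is lower in every library given drp1 dsRNA than in every other library of its experiment, and SMED30002662 is 58.6-fold and 45.9-fold lower with sod2 RNAi at homo and 1dpa.

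More features of control tails differed from 0dpa at 6hpa than at 1dpa or 2dpa, and the largest rise named here came at 2dpa. SMED30004725 rose from 13.1 ± 17.8 to 814 ± 152 at 6hpa, in the authors' scaled values (SD, n = 3), a log2 fold change of 7.01 with an SE of 0.7 (limma, adjusted p = 1.01e-09). SMED30015328 fell 15.2-fold by then, from 2910 ± 914 to 191 ± 66.5. By 1dpa SMED30022580 had risen 60.5-fold to 219 ± 36.9 and SMED30004333 had fallen 7.56-fold to 59.9 ± 7.82. SMED30028552 rose 69.8-fold at 1dpa and 225-fold at 2dpa, from 1.29 ± 1.4 to 143 ± 47.8 and then 499 ± 279. SMED30009224 fell 13-fold and then 16.6-fold, from 169 ± 21 to 12.3 ± 3.36 and 9.26 ± 1.01. Against 0dpa, limma called 8938 features at 6hpa (4068 higher, 4870 lower), 2845 at 1dpa (1423 higher, 1422 lower) and 3729 at 2dpa (2007 higher, 1722 lower). Changes over 2-fold numbered 2093 up and 1889 down at 6hpa, 386 and 212 at 1dpa, and 696 and 275 at 2dpa. The median of all features moved by -0.15 in log2 at 6hpa. The share of calls that were higher, 45.5%, 50% and 53.8%, depended on scaling. It was 22.5%, 88.9% and 93.9% on the TPM table, with medians of all features of -0.32, 0.22 and 0.35, and 34.8%, 65.8% and 75.3% without the most abundant feature, with medians of -0.30, 0.13 and 0.19. TMM rescaling gave 50.2%, 40.7% and 42.1%, and fits of only the libraries compared gave 53.3% at 6hpa. The 1dpa count fell to 1378 without control 0dpa replicate 1 and 1428 without control 1dpa replicate 3, while the 2dpa count fell to 2264 without control 2dpa replicate 2.

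In control whole bodies, features that had risen in amputated tails were higher at 1dpa than at homo. SMED30022580, which rose 60.5-fold in tails, was 11.6-fold higher here, at 8.17 ± 0.188 against 0.696 ± 0.0729 CPM (SD, n = 3; edgeR, adjusted p = 3.56e-10). SMED30028552 was 15.9-fold higher, at 44.6 ± 11 against 2.78 ± 1.84 CPM. SMED30004187 was at 0 in all 3 homo libraries and at 1.94 ± 0.263 CPM at 1dpa. SMED30009537 and SMED30035264 fell 13.8-fold and 4.84-fold, the latter from 56.2 ± 10.9 to 11.6 ± 1.64 CPM. Of 199 features chosen for their rise in tails at 2dpa, 135 were called higher and 1 (SMED30033019, named after its value was seen) lower in whole bodies, with a median log2 fold change of 0.67 (camera, adjusted p = 5.42e-48). The 198 chosen for their fall in tails at 2dpa had a median of -0.39 (camera, adjusted p = 3.4e-17). In the other direction, the 196 features chosen for their rise in whole bodies had medians of 0.16, 0.67 and 1.06 in control tails at 6hpa, 1dpa and 2dpa (camera, adjusted p = 0.00693, 1.55e-11 and 3.51e-30). The first of these calls was lost with an estimated correlation (camera, adjusted p = 0.281 with an estimated correlation). At 2dpa 105 of the 196 were called higher and 2 lower. These last, named after their values were seen, were SMED30029780 and SMED30009224, the latter among the largest falls in tails and at -4.05 in log2 there. Across features, the whole-body change correlated with that of tails at r = 0.129, 0.166 and 0.313 for 6hpa, 1dpa and 2dpa. In all, edgeR called 4285 features in control whole bodies, 2250 higher and 2035 lower at 1dpa, a balance that turned with RLE size factors (48.4% higher) and DESeq2 (47.7%).

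Opa1 RNAi lowered some abundant tail features at every time. SMED30028679 was lower than in control tails by log2 fold changes of -1.33, -2.19, -1.45 and -0.94 at 0dpa, 6hpa, 1dpa and 2dpa (limma, highest adjusted p = 0.000292). At 6hpa it stood at 601 ± 86.5 against 2760 ± 415 in the authors' scaled values (SD, n = 3). SMED30014993 rose 4.67-fold at 0dpa, 5.44-fold at 1dpa and 5.68-fold at 2dpa, reaching 117 ± 21 against 19.7 ± 1.58 at 2dpa. SMED30004394 and SMED30007040, which at 2dpa were at 158 ± 108 and 258 ± 136 in control tails, were 9.15-fold and 6.62-fold lower with opa1 RNAi, at 14.1 ± 4.78 and 37.9 ± 18.6 (limma, adjusted p = 7.88e-05 and 3.62e-05). At 6hpa SMED30026190 was at 568 ± 136 against 16.2 ± 10.3, a log2 fold change of 5.26 with an SE of 0.7 (limma, adjusted p = 2.3e-05).

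By count, limma called 51 features with opa1 RNAi at 0dpa (23 higher, 28 lower), 317 at 6hpa (127 higher, 190 lower), 106 at 1dpa (53 higher, 53 lower) and 210 at 2dpa (115 higher, 95 lower). Pairs of times shared 21 to 44 called features with the same sign. A test of the difference in effect between times gave 0 features by limma for 6hpa against 0dpa, with 1618 at an unadjusted p under 0.05 and no other tool run. It gave 3 for 1dpa and 10 for 2dpa, named here after their values were seen. Those at 1dpa were SMED30007457, SMED30035512 and SMED30015328, with differences of 0.78, 0.88 and 1.98 (limma, adjusted p = 0.032, 0.00763 and 0.039). At 2dpa SMED30026190 had a difference of -6.18 with an SE of 0.99 and SMED30007040 one of -3.09 with an SE of 0.56 (limma, adjusted p = 0.00165 and 0.00965). With 1 library left out these counts of differences ran from 0 to 32 at 6hpa (without control 6hpa replicate 2), from 0 (without opa1 RNAi 0dpa replicate 2 or control 1dpa replicate 1) to 13 (without opa1 RNAi 1dpa replicate 2) at 1dpa, and from 5 to 17 at 2dpa (without control 2dpa replicate 1 and opa1 RNAi 0dpa replicate 1). The counts against control moved too. Fits of only the libraries compared gave 22, 22, 43 and 789 calls, and leaving out 1 library gave as few as 22 at 0dpa (without control replicate 2), 127 to 727 at 6hpa (without control replicates 1 and 2), 40 to 390 at 1dpa (without control replicate 1 and opa1 RNAi replicate 2) and as few as 85 at 2dpa (without opa1 RNAi replicate 2). The share of calls that were higher, 45.1%, 40.1%, 50% and 54.8%, was 89.2%, 98.3%, 86.6% and 62.6% on the partial TPM table. Its median change at 6hpa was 0.26. At 2dpa the share was 69.2% with TMM rescaling and 42.4% without the most abundant feature, which gave 35.9% at 1dpa. At 2dpa it was also 41.1% in the fit of only the libraries compared, 45.5% without the 6hpa libraries and 46.6% over 2-fold.

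One feature took a large part of every tail library and was lower in opa1 RNAi than in control tails. SMED30032887, singled out after its values were seen, was the most abundant feature in all 36 tail libraries, at 3.61% to 29.2% of the summed values, and its levels in whole bodies were not analysed here. What kind of RNA it is was not determined. In control tails its share was 13.9% ± 1.2 at 0dpa, 25.1% ± 4 at 6hpa, 9.7% ± 0.17 at 1dpa and 8.77% ± 1.1 at 2dpa (SD, n = 3). With opa1 RNAi it was 7.6% ± 1.3, 11.5% ± 1.7, 4.23% ± 0.18 and 4.41% ± 0.72 (SD, n = 3). With drp1 RNAi added it was 11.1% ± 0.6, 21.5% ± 2.4, 8.27% ± 0.074 and 7.28% ± 0.83 (SD, n = 3). Averaged over the 4 times on a log2 scale, its share with opa1 RNAi was 48.4% of that in control tails, and combined RNAi stood at 173% of opa1 RNAi alone and at 83.6% of control. An exact two-sided permutation test within times, in a family of 3 comparisons, gave p = 1.25e-05, 1.25e-05 and 0.000125 for these, and 1.88e-05, 1.88e-05 and 0.000125 after Benjamini-Hochberg adjustment. The value of 1.25e-05 is the smallest such permutations can give. Per time, limma gave log2 fold changes with opa1 RNAi of -0.95, -1.38, -1.25 and -1.02 (adjusted p = 0.058, 0.000639, 0.00232 and 0.0139), so the first did not pass. When drp1 RNAi was added they were 0.61, 1.19, 1.02 and 0.74 by limma (adjusted p = 0.162, 0.00294, 0.0284 and 0.16), of which 6hpa and 1dpa passed.

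**Figure D3:**
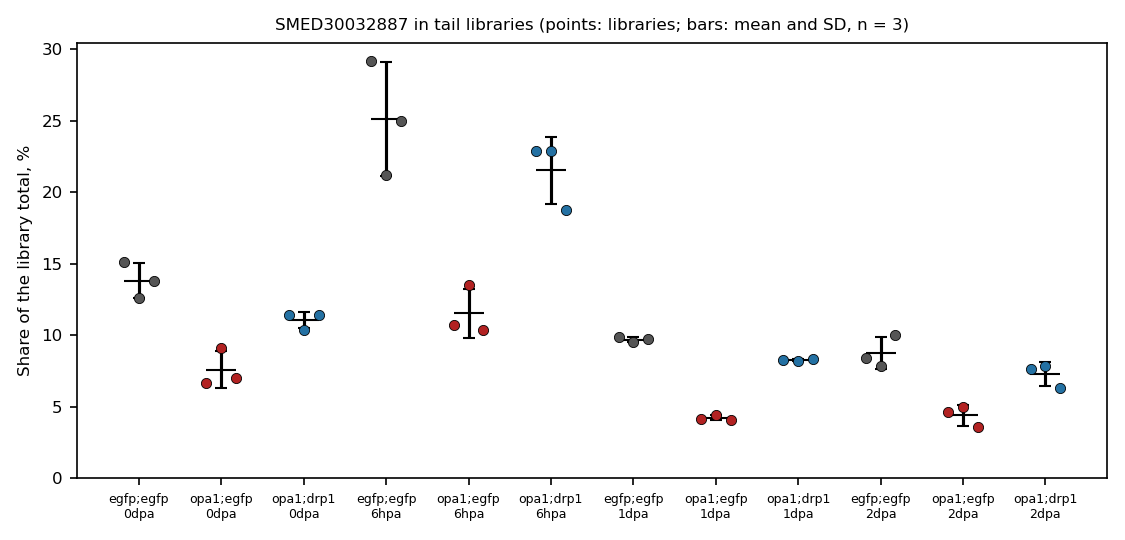
Share of SMED30032887 in the summed values of each tail library, in percent, by RNAi and time. Points are libraries and bars are the mean with the SD of 3 libraries. Control tails average 25.1% at 6hpa, opa1 RNAi tails 11.5% and combined RNAi tails 21.5%.

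Some of the tail features changed by opa1 RNAi moved the other way when drp1 RNAi was added. SMED30012212, among the 2 largest rises on adding drp1 RNAi at 1dpa, stood at 11500 ± 942 in control tails, 2760 ± 275 with opa1 RNAi and 7290 ± 605 with both (SD, n = 3; limma log2 fold change on adding drp1 1.40 with an SE of 0.15, adjusted p = 3.07e-07). SMED30008414 stood at 713 ± 177, 180 ± 34.3 and 468 ± 23.9 in the same groups. At 0dpa SMED30015328 stood at 2910 ± 914 in control tails, 932 ± 275 with opa1 RNAi and 4110 ± 842 with both, a 4.47-fold rise on adding drp1 RNAi (limma, adjusted p = 6.55e-06). SMED30023781 rose 3.21-fold at 2dpa, to 120 ± 13.9 from 36.6 ± 5.56, with control tails at 41.3 ± 13.7. At 6hpa SMED30022580 fell 7.19-fold on adding drp1 RNAi (limma, adjusted p = 0.000465). SMED30006900 fell 5.01-fold at 0dpa, from 148 ± 21.8 to 29.3 ± 8.09, with control tails at 124 ± 27.4.

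In this comparison limma called 158 features at 0dpa (45 higher, 113 lower), 984 at 6hpa (496 higher, 488 lower), 62 at 1dpa (17 higher, 45 lower) and 152 at 2dpa (55 higher, 97 lower). Features that moved one way with opa1 RNAi and the other way on adding drp1 RNAi numbered 19, 122, 29 and 50 from 0dpa to 2dpa, of which 10, 36, 16 and 28 had risen with opa1 RNAi, where independent lists would share 0.126, 3, 0.115 and 0.539, and 9, 86, 13 and 22 had fallen, against 0.0609, 4.56, 0.0436 and 0.253. The opa1 RNAi libraries enter both comparisons, which alone makes their fold changes move apart. Simulated unchanged groups shared 0 such calls, which does not show what sharing adds where effects are real. The covariance of fold changes was -0.13, -0.2, -0.0865 and -0.113 against -0.0846, -0.083, -0.0854 and -0.0853 in simulation. The simulation used a single spread per feature for all tail times, while pairs of replicates correlated at 0.9456 to 0.962 at 6hpa and 0.9725 to 0.9772 at 2dpa. It therefore does not give what sharing adds at each time. The 3 opa1 RNAi libraries of a time could not be split, and part of the excess of shared calls may come from sharing them. Fits of only the libraries compared gave 346, 67, 35 and 691 calls. At 6hpa such fits called 22 with opa1 RNAi, so the 122 above could not be reached in them. With 1 library left out (named below), counts were 36 to 314 at 0dpa and 309 to 1610 at 6hpa. They were 29 to 145 at 1dpa and as few as 64 at 2dpa. The share of calls that were higher, 28.5%, 50.4% and 36.2% at 0dpa, 6hpa and 2dpa, was 5.8% at 0dpa and 1.99% at 6hpa on the TPM table, with a median of all features of -0.26 at 6hpa, 12.9% at 2dpa with TMM rescaling, and 21.9% at 6hpa and 48.6% at 2dpa without the most abundant feature. At 2dpa the balance turned in the fit of only the libraries compared (393 higher, 298 lower) and without the 6hpa libraries (161 higher, 127 lower).

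Combined RNAi tails still differed from control tails. Over all tail libraries limma called 75 features at 0dpa (20 higher, 55 lower), 126 at 6hpa (41 higher, 85 lower), 49 at 1dpa (17 higher, 32 lower) and 77 at 2dpa (14 higher, 63 lower). The shares that were higher at 0dpa and 1dpa, 26.7% and 34.7%, were 50% and 46.7% on the TPM table, and without the most abundant feature they were 13.8% at 0dpa and 12.7% at 6hpa. In the fit of only the libraries compared 34 were higher and 32 lower at 0dpa. Of the features called with opa1 RNAi, 5, 12, 5 and 9 were higher here too from 0dpa to 2dpa, where independent lists would share 0.0222, 0.252, 0.0436 and 0.0778, and 3, 10, 4 and 23 lower, against 0.0745, 0.781, 0.082 and 0.289. Both comparisons use the same 3 control libraries, from which part of the excess may come, and simulated unchanged groups, which shared 0, do not show how much. Covariances of fold changes were 0.089, 0.12, 0.0817 and 0.0797, against 0.085, 0.0837, 0.0858 and 0.0859 in simulation. The simulation does not give what sharing adds at each time. Whether the effects of opa1 and combined RNAi differ was tested only by comparing these groups directly, as given for the addition of drp1 RNAi. SMED30027152 was at 99 ± 29.8 at 0dpa against 1120 ± 26 in control tails (SD, n = 3). With 1 library left out (named below), counts ran from 13 to 197 at 0dpa and 49 to 222 at 6hpa. They fell as low as 17 at 1dpa and 43 at 2dpa. Fits of only the libraries compared gave 7 at 6hpa, 148 at 1dpa and 252 at 2dpa.

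In whole bodies at homo, opa1 RNAi and drp1 RNAi changed many of the same features. SMED30002753 rose 9.46-fold with opa1 RNAi, from 42.4 ± 6.99 to 401 ± 87.3 CPM (SD, n = 3), a log2 fold change of 3.24 with an SE of 0.15 (edgeR, adjusted p = 5.44e-16). It also rose with drp1 RNAi, by 1.90 in log2. SMED30022580, which rose in amputated control tails, rose 3.82-fold with opa1 RNAi, from 0.696 ± 0.0729 to 2.67 ± 0.881 CPM (edgeR, adjusted p = 0.000104), and SMED30025990 fell 6.93-fold. SMED30028552, which rose 225-fold in control tails at 2dpa, was 13.1-fold higher with drp1 RNAi, at 36.7 ± 4.67 against 2.78 ± 1.84 CPM (edgeR, adjusted p = 7.55e-09). SMED30017639 rose 12.3-fold with drp1 RNAi, from 7.13 ± 4.75 to 87.7 ± 10.9 CPM, and SMED30005177 fell 6.66-fold, from 9.17 ± 3.34 to 1.38 ± 0.959 CPM.

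For opa1 RNAi at homo, edgeR called 7961 features, 4395 higher and 3566 lower, and falls over 2-fold (1330) outnumbered rises (256). For drp1 RNAi it called 5555, 3147 higher and 2408 lower, with 300 rises and 623 falls over 2-fold. Both called 2597 features higher and 1569 lower, where independent lists would share 604 and 375, and 22 were called in opposite directions. Fold changes correlated at r = 0.702 across features, against 0.494 for simulated unchanged groups with the same controls, and their covariance was 0.271 against 0.0598. Compared directly, opa1 and drp1 RNAi differed in 912 features at homo by edgeR, 551 higher and 361 lower with opa1 RNAi, a balance that turned over 2-fold (36 higher, 82 lower). The controls are too few to split, so part of the excess may come from sharing them. The shares of calls that were higher, 55.2%, 56.7% and 60.4% for these comparisons, were 24.3%, 18.4% and 83.1% on TPM, which moved the median of all features by -0.19 for opa1 and -0.20 for drp1 RNAi, and the first was 49.4% in the fit of only the libraries compared. Without control replicate 3 the counts were 5128 for opa1 and 3135 for drp1 RNAi, and the direct comparison gave as few as 478 without drp1 RNAi replicate 2, as well as 542 and 586 without drp1 RNAi replicates 1 and 3 and 514 without opa1 RNAi replicate 1.

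At 1dpa more whole-body features differed between opa1 and drp1 RNAi than at homo, a comparison of counts and not a test. SMED30008414 fell 8.92-fold with opa1 RNAi, from 117 ± 20.1 to 13.1 ± 2.59 CPM (SD, n = 3; edgeR, adjusted p = 9.91e-09), and SMED30010476 rose 4.68-fold, from 4.12 ± 0.823 to 19.3 ± 3.14 CPM (edgeR, adjusted p = 2.23e-06). With drp1 RNAi SMED30002911 rose 13.5-fold, from 11.5 ± 5.94 to 155 ± 34.7 CPM (edgeR, adjusted p = 5.12e-07), and SMED30011896 fell 5.25-fold, from 4.51 ± 0.971 to 0.85 ± 0.112 CPM. Opa1 RNAi gave 2564 calls by edgeR (1045 higher, 1519 lower) and drp1 RNAi 1645 (877 higher, 768 lower), of which 325 were higher and 250 lower in both, where independent lists would share 40 and 51, and 22 were opposite. The correlation across features was 0.425, below the 0.508 of simulated groups with the same controls, while the covariance was 0.0807 against 0.0539. Between opa1 and drp1 RNAi directly, edgeR called 3414 features, 1285 higher and 2129 lower with opa1 RNAi. The shares that were higher, 40.8%, 53.3% and 37.6%, were 93%, 74% and 87.2% on TPM, which moved the median of all features by 0.25 for opa1 RNAi and by 0.21 for opa1 against drp1 RNAi. For drp1 RNAi the share was 46.6% in the fit of only the libraries compared and 36.4% over 2-fold, and between opa1 and drp1 RNAi it was 54.1% over 2-fold. Counts fell to 1503, 1586 and 1698 for opa1 RNAi without opa1 RNAi replicate 1, control replicate 1 or control replicate 3, to 894 and 970 for drp1 RNAi without drp1 RNAi replicate 3 or control replicate 2, and to as few as 1967 between them without drp1 RNAi replicate 1.

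For opa1 RNAi, many whole-body features moved one way at homo and the other way at 1dpa. Of the features called at both times, 458 had the same sign and 958 opposite signs, and fold changes at the homo and 1dpa times correlated at r = -0.106 across features. Of the same-sign features 372 were higher and 86 lower at both, where independent lists would share 201 and 237. SMED30028679 and SMED30002753, followed here after their values were seen, differed in course. The first had a log2 fold change of -0.27 at homo (edgeR, adjusted p = 0.136) and -2.23 at 1dpa (edgeR, adjusted p = 3.73e-12), a difference of -1.96 with an SE of 0.2. The second rose at both, by 3.24 and 1.60, a difference of -1.64 (edgeR, adjusted p = 4.53e-07). The test of the difference called 6524 features by edgeR, 2931 with a higher and 3593 with a lower effect at 1dpa, a balance that turned over 2-fold (1271 higher, 798 lower). Drp1 RNAi instead had 913 features with the same sign at homo and 1dpa and 43 opposite, r = 0.34, and 897 features whose effect differed (235 higher, 662 lower at 1dpa). The shares of differences that were higher, 44.9% for opa1 and 26.2% for drp1 RNAi, were 90.6% and 89.9% on TPM, which moved the median of all features by 0.44 and 0.24. For drp1 RNAi the count of differences was 2346 on TPM, 498 in a fit of only these libraries, and 366 to 1440 with 1 library left out (without control homo replicates 3 and 1).

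**Figure D4:**
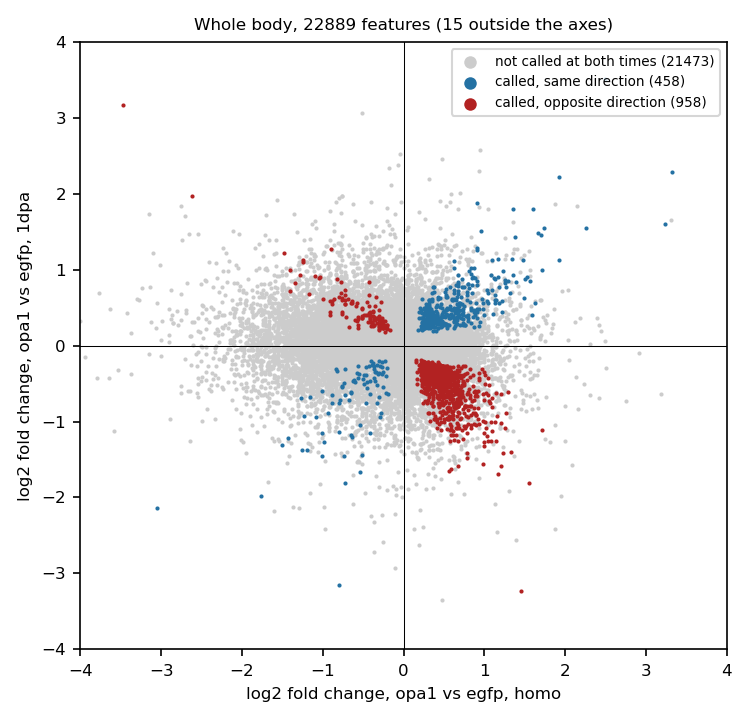
Log2 fold change of opa1 RNAi against control whole bodies at homo on the x axis and at 1dpa on the y axis, one point per feature for 22889 features. Colours mark the 458 features called at both times with the same sign, the 958 with opposite signs and the 21473 not called at both, and 15 points lie outside the axes.

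Sod2 RNAi changed fewer whole-body features than opa1 or drp1 RNAi, a comparison of counts and not a test. SMED30003686 fell 13.9-fold at 1dpa, from 106 ± 4.69 to 7.63 ± 1.18 CPM (SD, n = 3), a log2 fold change of -3.80 with an SE of 0.15 (edgeR, adjusted p = 1.99e-18). Its fall at homo was -1.68, and the difference between times was -2.11 with an SE of 0.2 (edgeR, adjusted p = 1.19e-07). SMED30021024 rose 4.33-fold at 1dpa, from 1.26 ± 0.37 to 5.47 ± 1.64 CPM (edgeR, adjusted p = 0.00199). At homo SMED30013580 fell 11.9-fold, from 2.21 ± 0.931 to 0.177 ± 0.0402 CPM (edgeR, adjusted p = 0.00253), and at 1dpa it stood at 26.7 ± 7.03 with sod2 RNAi and 23.5 ± 6.17 in controls. At the homo time edgeR called 862 features (493 higher, 369 lower) and at 1dpa 90 (49 higher, 41 lower), and 44 were called at both with the same sign. The balance at homo turned in the fit of only the libraries compared (272 higher, 373 lower) and for changes over 2-fold (25 higher, 103 lower), as did that at 1dpa (5 higher, 18 lower). SMED30028423, named after its values were seen, was called at both with opposite signs, at -0.29 and 0.35. At homo 294 features were higher and 152 lower with both sod2 and opa1 RNAi, where independent lists would share 94.7 and 57.5, and 208 and 129 with both sod2 and drp1 RNAi, against 67.8 and 38.8. At 1dpa sod2 RNAi shared 39 higher and 30 lower with opa1 RNAi, against 2.24 and 2.72, and 41 and 13 with drp1 RNAi, against 1.88 and 1.38. In opposite directions to opa1 and drp1 RNAi were 101 and 118 at homo and 3 and 2 at 1dpa. Part of the excess may come from the shared controls, and simulated unchanged groups, which shared at most 1, do not show how much. Covariances of fold changes at homo were 0.122 with opa1 and 0.0996 with drp1 RNAi, against 0.0598 and 0.0591 in simulation, and at 1dpa 0.0592 and 0.0707 against 0.054 and 0.0535. Correlations across features lay below simulation, at 0.428 and 0.39 against 0.508 and 0.499 at homo and at 0.397 and 0.462 against 0.51 and 0.492 at 1dpa. The shares that were higher, 57.2% and 54.4%, were 86.6% and 70.5% on TPM. Counts with 1 library left out (named below) fell as low as 304 at homo and 49 at 1dpa. A fit of only the libraries compared gave 208 at 1dpa.

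Features that changed in whole bodies were then followed in tails, which share no libraries with them. The 196 features chosen as higher at 1dpa than at homo in control whole bodies were lower with opa1 RNAi than in control tails, with median log2 fold changes of -0.15, -0.28, -0.32 and -0.33 from 0dpa to 2dpa (camera, adjusted p = 0.00767, 0.000222, 6.54e-10 and 4.24e-08). The 0dpa and 6hpa calls were lost with an estimated correlation (camera, adjusted p = 0.281 and 0.106 with an estimated correlation). In combined RNAi against control tails their medians were -0.13, -0.16, -0.23 and -0.11 (camera, adjusted p = 0.0326, 0.000161, 6.33e-12 and 4.25e-10), where 0dpa and 6hpa were again lost (camera, adjusted p = 0.387 and 0.0956 with an estimated correlation). On adding drp1 RNAi to opa1 RNAi their medians of 0.03, 0.11, 0.07 and 0.10 did not pass (camera, adjusted p = 0.865, 0.879, 0.861 and 0.58). With all called features in the set, those at 1dpa and 2dpa did (camera, adjusted p = 8.92e-05 and 0.0443).

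The 191 features chosen as raised by opa1 RNAi in whole bodies at homo were higher in opa1 RNAi than in control tails, and lower in combined than in opa1 RNAi tails. The opa1 RNAi libraries enter both comparisons, so the opposite movements here and below are not independent of each other. Their medians with opa1 RNAi were 0.21, 0.05, 0.12 and 0.33 (camera, adjusted p = 4.57e-12, 0.00765, 7.63e-08 and 2.25e-19), the call at 6hpa being lost with an estimated correlation (camera, adjusted p = 0.281 with an estimated correlation). On adding drp1 RNAi they were -0.16, -0.05, -0.10 and -0.25 (camera, adjusted p = 6.23e-05, 0.0493, 1.35e-07 and 2.82e-17), with 0dpa and 6hpa lost (camera, adjusted p = 0.0718 and 0.414 with an estimated correlation). In combined RNAi against control tails they were 0.06, -0.01, 0.04 and 0.11 (camera, adjusted p = 0.0822, 0.75, 0.291 and 0.0332), the last lost with an estimated correlation (camera, adjusted p = 0.387 with an estimated correlation). With all called features in the set, the 0dpa and 6hpa calls with opa1 RNAi were lost (camera, adjusted p = 0.0715 and 0.289), and on adding drp1 RNAi the 0dpa test turned direction and the 6hpa call was lost (camera, adjusted p = 0.678 and 0.41). SMED30002753, a member of this group, was at 1090 ± 180 in control tails, 3760 ± 226 with opa1 RNAi and 1810 ± 229 with both at 2dpa, in the authors' scaled values (SD, n = 3). The 66 features raised over 2-fold by opa1 RNAi at 1dpa had medians of 0.18, 0.09, 0.22 and 0.15 with opa1 RNAi (camera, adjusted p = 0.0007, 0.00142, 1.35e-05 and 2.31e-06) and of -0.02, -0.08, -0.18 and -0.17 on adding drp1 RNAi (camera, adjusted p = 0.274, 0.0349, 4.6e-08 and 2.26e-05). Of these 0dpa did not pass and 6hpa was lost with an estimated correlation (camera, adjusted p = 0.188 with an estimated correlation). With all called features in this set, the 0dpa and 6hpa calls with opa1 RNAi were lost (camera, adjusted p = 0.0844 and 0.276), while on adding drp1 RNAi 0dpa passed and 6hpa turned direction (camera, adjusted p = 0.000174 and 0.206). The 189 chosen as lowered by opa1 RNAi at homo had medians of -0.33, -0.28, -0.16 and -0.39 in opa1 RNAi tails (camera, adjusted p = 1.33e-06, 0.000788, 0.0175 and 1.7e-07). All of these were lost with an estimated correlation (camera, adjusted p = 0.387, 0.583, 0.74 and 0.355 with an estimated correlation).

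The 18 features lowered over 2-fold by sod2 RNAi in whole bodies at 1dpa were lower in opa1 RNAi than in control tails at 1dpa and 2dpa. At 2dpa 10 of the 18 were called lower and 1 (SMED30001799, named after its values were seen) higher, with a median of -0.76 (camera, adjusted p = 1.24e-20). At 1dpa 7 were lower and 1 higher, with a median of -0.36 (camera, adjusted p = 7.68e-10), a call lost with an estimated correlation (camera, adjusted p = 0.109 with an estimated correlation). Medians at 0dpa and 6hpa were 0.01 and -0.14, the latter with the test pointing up, and neither passed (camera, adjusted p = 0.474 and 0.354). On adding drp1 RNAi the medians were 0.61 at 1dpa and 0.45 at 2dpa (camera, adjusted p = 3.91e-13 and 3.12e-08), both lost with an estimated correlation (camera, adjusted p = 0.0521 and 0.168 with an estimated correlation). SMED30003686 stood at 2430 ± 394 in control tails, 584 ± 118 with opa1 RNAi and 1130 ± 134 with both at 2dpa (SD, n = 3; limma log2 fold changes -2.06 and 0.97, adjusted p = 5.46e-10 and 0.00189).

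**Figure D5:**
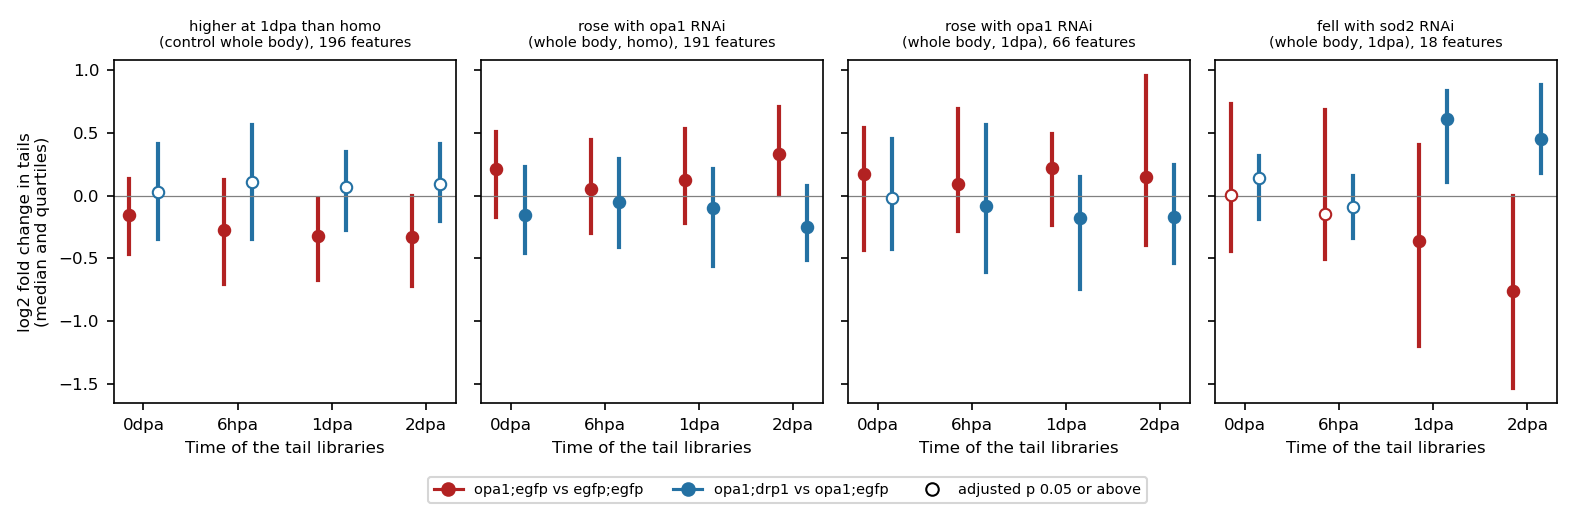
Median log2 fold change in tails of 4 groups of features chosen in whole bodies, by time after amputation, with lines for the quartiles over features. The groups are 196 features higher at 1dpa than at homo in controls, 191 up with opa1 RNAi at homo, 66 up with opa1 RNAi at 1dpa and 18 down with sod2 RNAi at 1dpa. Red is opa1 RNAi against control tails, blue is the addition of drp1 RNAi, and open symbols did not pass camera with the preset correlation.

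Tail features were likewise followed in whole bodies. Of the 16 raised over 2-fold by opa1 RNAi in tails at 1dpa, 14 were called higher with opa1 RNAi at homo, with a median of 1.34 (camera, adjusted p = 1.63e-21), and their median at 1dpa was 0.88 (camera, adjusted p = 3.38e-24). Of the 34 raised over 2-fold at 2dpa in tails, 24 were called higher at homo, with a median of 1.09, and the 1dpa median was 0.51 (camera, adjusted p = 2.99e-18 and 1.54e-15). The 38 lowered over 2-fold at 2dpa in tails went down with opa1 RNAi in whole bodies at 1dpa, median -0.51 (camera, adjusted p = 1.36e-08), and up with drp1 RNAi at homo, median 0.92 (camera, adjusted p = 1.59e-11). At homo with opa1 RNAi their median was 0.16 with the test pointing down, and it did not pass (camera, adjusted p = 0.955). These 38 were lower with opa1 than with drp1 RNAi at homo and 1dpa, with medians of -0.89 and -1.12 (camera, adjusted p = 1.06e-27 and 3.32e-26). With sod2 RNAi at homo the same 38 had a median of -0.51 (camera, adjusted p = 7.84e-11). At r = 0.202, 0.0837, 0.191 and 0.266 for tails from 0dpa to 2dpa, the fold changes of opa1 RNAi across all features in whole bodies at homo and in tails were weakly correlated.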

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

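The tests of exchanged libraries, exchanged time labels and other splits of the samples were chosen after the results were seen, while the test of scaling was fixed before. In whole bodies the effect of opa1 RNAi differed between homo and 1dpa in 6524 features by edgeR, as a test of the difference itself. Had opa1 and control libraries been exchanged at one time, SMED30010319, which was chosen in tails for its fall with opa1 RNAi, would have risen there, but its higher log2 fold change over both times was -2.14. Exchanged time labels among the opa1 libraries would turn the difference between times in them, yet features that rose in control tails at 2dpa had a median log2 change of 0.746 from homo to 1dpa in those libraries (quartiles 0.265 and 1.28), and 166 of 199 were higher. On median-centred TPM, 67% of features called at both times (675 of 1007) had opposite signs, and 67.7% (958 of 1416) with edgeR. TMM also centres the changes, so this does not decide on scaling. Of 40 splits of these libraries, 1, the real one, gave as many features as its 5959 in a fit of these libraries alone. The highest of the others was 870, in a split that exchanged the RNAi groups at homo whole and so carries their effect. Splits that mixed the groups at both times reached 0. The share of 0.025 is the smallest that 40 splits can give, so chance is argued against but not excluded. A change of the opa1 RNAi effect between homo and 1dpa stays open as a hypothesis, since scaling was not decided and a library or sequencing batch was not tested.

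The other differences between times were smaller. For drp1 RNAi in whole bodies edgeR called 897 features whose effect differed between homo and 1dpa. In a fit of these libraries alone there were 498, which 2 of 40 splits reached, with 820 as the highest of the others. The split with 820 exchanged the RNAi groups at homo whole and so carries their effect, and splits that mixed the groups at both times reached 1 at most, so this count does not decide on chance. For sod2 RNAi edgeR called 33, and 64 in the fit of these libraries alone, reached by 5 of 40 splits with 187 as the highest of the others. The split with 187 left the homo groups as they were, and splits that mixed the groups at both times reached 0, so this does not decide either. Of the 33, SMED30003686 had a difference of -2.11 with an SE of 0.2 (edgeR, adjusted p = 1.19e-07) and SMED30013580 one of 3.76 with an SE of 0.72 (edgeR, adjusted p = 0.0163). Leaving out 1 library moved this count between 9 (without sod2 RNAi 1dpa replicate 1) and 76 (without control homo replicate 3).

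In tails the effect of opa1 RNAi differed from that at 0dpa in 3 features at 1dpa and 10 at 2dpa by limma. The 3 are SMED30007457, SMED30035512 and SMED30015328, and 7 of the 10 were lower at 2dpa. Leaving out 1 library moved these counts between 0 (without opa1 RNAi 0dpa replicate 2 or control 1dpa replicate 1) and 13 (without opa1 RNAi 1dpa replicate 2) at 1dpa and between 5 and 17 at 2dpa (without control 2dpa replicate 1 and opa1 RNAi 0dpa replicate 1). Separate fits of these libraries by limma gave 0 at 6hpa and 0 at 1dpa, where limma over all tail libraries had 1618 and 1257 features at an unadjusted p under 0.05, and no other tool was run. A count of 0 is reached by any split, so the 100 of 100 splits that reached it say nothing of chance. The highest of the others were 110 and 28, in splits that mixed the RNAi groups at both times, and the cause of these counts was not tested. At 2dpa the separate fit gave 12, reached by 6 of 100 splits with 115 as the highest of the others. The split with 115 exchanged the RNAi groups at 2dpa whole, and splits that mixed the groups at both times reached 2 at most, so chance is not decided here.

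All other comparisons set 3 libraries against 3, which make 10 splits, too few for a share under 0.05. In fits of only the libraries compared, opa1 RNAi against control tails gave 22, 22, 43 and 789 features from 0dpa to 2dpa, the addition of drp1 RNAi 346, 67, 35 and 691, and combined RNAi against control tails 66, 7, 148 and 252. Control tails against 0dpa gave 6736, 3331 and 4180. In whole bodies, opa1, drp1 and sod2 RNAi gave 5771, 4749 and 645 at homo and 3099, 1170 and 208 at 1dpa, opa1 against drp1 RNAi 946 and 2727, and control times against each other 3359. The highest of the other splits was at most 2 in each of these.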

How the results depend on the processing

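All values in this part were computed for alternatives fixed in advance, except for TMM rescaling of the tail values, a pseudocount of 0.1 on them, the fit without the 6hpa libraries and the fit without the largest tail feature, which were tests chosen after the data were seen. Directions held throughout for the named features: of their values, 392 kept their call and 40 lost it when 1 library was left out, and 613 kept and 21 lost it in the other settings, and none changed sign. RLE size factors in the whole body and TMM rescaling in the tails moved no count by over 1.5 times. Counts of calls not listed for a setting stayed within 1.5 times those reported. The cause was not tested for any change below other than those that follow from how the alternative is built, such as a fold threshold or fewer libraries. With 3 libraries per group and these totals, simulated 2-fold changes were recovered in 65.7% of cases for whole-body opa1 RNAi at homo and in 50.5% for opa1 RNAi tails at 1dpa, and depth was not varied, so its part in this was not separated from that of spread and replicate number. RLE factors and DESeq2 were not run on the tail values, which are not counts, sums over isoforms were not run since the IDs name none, and gene list tests and the TPM check of the targeted genes were not run since no feature could be matched to a name.

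With an absolute log2 fold change over 1 also required, counts of called features were 31 at 0dpa, 156 at 6hpa, 39 at 1dpa and 73 at 2dpa in opa1 RNAi against control tails, with 41 at 0dpa, 328 at 6hpa, 27 at 1dpa and 53 at 2dpa in the addition of drp1 RNAi. The same choice gave 30 at 0dpa, 71 at 6hpa, 32 at 1dpa and 50 at 2dpa in combined RNAi against control tails, with 3982 at 6hpa, 598 at 1dpa and 971 at 2dpa in control tails against 0dpa. It also gave 1 at 1dpa and 6 at 2dpa in the change of the tail opa1 RNAi effect from 0dpa, with 1586 for opa1 at homo, 923 for drp1 at homo, 128 for sod2 at homo, 263 for opa1 at 1dpa, 231 for drp1 at 1dpa and 23 for sod2 at 1dpa in whole-body RNAi against control. Further counts were 118 at homo and 375 at 1dpa in whole-body opa1 against drp1 RNAi, with 449 for 1dpa against homo in control whole bodies. Further counts were 2069 for opa1, 187 for drp1 and 16 for sod2 in the whole-body change of effect from homo to 1dpa.

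With limma on the deposited TPM and a pseudocount of 1, counts were 6888 for opa1 at 1dpa in whole-body RNAi against control, with 2346 for drp1 and 15 for sod2 in the whole-body change of effect from homo to 1dpa. The same choice gave 111 at 0dpa, 3749 at 6hpa and 172 at 1dpa in opa1 RNAi against control tails, with 379 at 0dpa, 4075 at 6hpa and 92 at 2dpa in the addition of drp1 RNAi. It also gave 14 at 0dpa, 12 at 6hpa and 30 at 1dpa in combined RNAi against control tails, with 0 at 1dpa and 19 at 2dpa in the change of the tail opa1 RNAi effect from 0dpa. With a pseudocount of 0.1 and no filter, TPM gave 6091 for opa1 at 1dpa in whole-body RNAi against control, with 1998 for drp1 and 21 for sod2 in the whole-body change of effect from homo to 1dpa. That pseudocount also gave 120 at 0dpa and 3765 at 6hpa in opa1 RNAi against control tails, with 313 at 0dpa, 4145 at 6hpa and 90 at 2dpa in the addition of drp1 RNAi. The unfiltered TPM gave 20 at 0dpa, 22 at 6hpa and 28 at 1dpa in combined RNAi against control tails, with 1 at 1dpa in the change of the tail opa1 RNAi effect from 0dpa. With no filter on low counts, edgeR gave 192 for sod2 at 1dpa in whole-body RNAi against control, with 148 for sod2 in the whole-body change of effect from homo to 1dpa. DESeq2 gave 120 for sod2 in the whole-body change of effect from homo to 1dpa.

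With no filter on low tail values, limma gave 203 at 6hpa in opa1 RNAi against control tails, with 68 at 0dpa and 625 at 6hpa in the addition of drp1 RNAi. Unfiltered tails gave 46 at 0dpa and 79 at 6hpa in combined RNAi against control tails, with 1 at 1dpa in the change of the tail opa1 RNAi effect from 0dpa. Fits of only the libraries compared gave 208 for sod2 at 1dpa in whole-body RNAi against control, with 498 for drp1 and 64 for sod2 in the whole-body change of effect from homo to 1dpa. Such separate fits gave 22 at 0dpa, 22 at 6hpa, 43 at 1dpa and 789 at 2dpa in opa1 RNAi against control tails, with 346 at 0dpa, 67 at 6hpa, 35 at 1dpa and 691 at 2dpa in the addition of drp1 RNAi. They also gave 7 at 6hpa, 148 at 1dpa and 252 at 2dpa in combined RNAi against control tails, with 0 at 1dpa in the change of the tail opa1 RNAi effect from 0dpa. A pseudocount of 0.1 on the tail values gave 201 at 6hpa in combined RNAi against control tails, with 2 at 6hpa in the change of the tail opa1 RNAi effect from 0dpa. Without the largest tail feature, limma gave 304 at 0dpa in the addition of drp1 RNAi, with 138 at 0dpa in combined RNAi against control tails. Leaving it out also gave 5 at 1dpa and 16 at 2dpa in the change of the tail opa1 RNAi effect from 0dpa. Without the 6hpa libraries, the tail counts were 97 at 0dpa, 173 at 1dpa and 369 at 2dpa in opa1 RNAi against control tails, with 682 at 0dpa, 98 at 1dpa and 288 at 2dpa in the addition of drp1 RNAi. The fit without 6hpa gave 173 at 0dpa, 75 at 1dpa and 120 at 2dpa in combined RNAi against control tails, with 20 at 2dpa in the change of the tail opa1 RNAi effect from 0dpa.

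For some set tests, adjusted p is listed where the call or direction differed from camera with the preset correlation. Sets are from the whole body unless called tail features. With estimated correlation, camera lost 67 tail and 49 whole-body calls, including these. Features higher at 1dpa than at homo in controls had 0.281 at 6hpa in control tails against 0dpa, and 0.281 at 0dpa and 0.106 at 6hpa in opa1 RNAi against control tails, and 0.387 at 0dpa and 0.0956 at 6hpa in combined RNAi against control tails. Features up with opa1 RNAi at homo had 0.281 at 6hpa in opa1 RNAi against control tails, and 0.0718 at 0dpa and 0.414 at 6hpa in the addition of drp1 RNAi, and 0.387 at 2dpa in combined RNAi against control tails. Features down with opa1 RNAi at homo had 0.387 at 0dpa, 0.583 at 6hpa, 0.74 at 1dpa and 0.355 at 2dpa in opa1 RNAi against control tails, and 0.455 at 6hpa and 0.548 at 2dpa in the addition of drp1 RNAi, and 0.526 at 0dpa and 0.771 at 2dpa in combined RNAi against control tails. Tail features up with opa1 RNAi at 1dpa had 0.408 at 1dpa in whole-body opa1 against drp1 RNAi. Tail features up with opa1 RNAi at 2dpa had 0.0844 at 1dpa in whole-body opa1 against drp1 RNAi. Tail features down with opa1 RNAi at 2dpa had 0.0557 for drp1 at 1dpa in whole-body RNAi against control. Features down with sod2 RNAi at homo had 0.29 at 6hpa in opa1 RNAi against control tails, and 0.0606 at 1dpa and 0.364 at 2dpa in the addition of drp1 RNAi. Features down with sod2 RNAi at 1dpa had 0.109 at 1dpa in opa1 RNAi against control tails, and 0.0521 at 1dpa and 0.168 at 2dpa in the addition of drp1 RNAi. Features up with opa1 RNAi at 1dpa had 0.188 at 6hpa in the addition of drp1 RNAi. With fry, which tests each set alone, these calls and others were lost unless marked. Features higher at 1dpa than at homo in controls had 0.0738 at 0dpa in opa1 RNAi against control tails, and 0.174 at 0dpa in combined RNAi against control tails. Features lower at 1dpa than at homo in controls had 0.00145 (call gained) at 6hpa in control tails against 0dpa. Features up with opa1 RNAi at homo had 0.136 at 6hpa in opa1 RNAi against control tails, and 0.33 at 6hpa in the addition of drp1 RNAi, and 0.232 at 2dpa in combined RNAi against control tails. Features down with opa1 RNAi at homo had 0.181 at 0dpa, 0.234 at 6hpa, 0.513 at 1dpa and 0.108 at 2dpa in opa1 RNAi against control tails, and 0.0719 at 6hpa and 0.234 at 2dpa in the addition of drp1 RNAi, and 0.315 at 0dpa and 0.781 at 2dpa in combined RNAi against control tails. Tail features up with opa1 RNAi at 1dpa had 0.0899 at 1dpa in whole-body opa1 against drp1 RNAi. Features down with sod2 RNAi at homo had 0.0541 at 6hpa in opa1 RNAi against control tails, and 0.0531 at 2dpa in the addition of drp1 RNAi. Features up with opa1 RNAi at 1dpa had 0.0754 at 6hpa in the addition of drp1 RNAi. With all called features in each set, camera lost calls where not marked otherwise. Features higher at 1dpa than at homo in controls had 0.119 at 0dpa in opa1 RNAi against control tails, and 8.92e-05 (call gained) at 1dpa and 0.0443 (call gained) at 2dpa in the addition of drp1 RNAi, and 0.314 at 6hpa in combined RNAi against control tails. Features up with opa1 RNAi at homo had 0.0715 at 0dpa and 0.289 at 6hpa in opa1 RNAi against control tails, and 0.678 (direction turned) at 0dpa and 0.41 at 6hpa in the addition of drp1 RNAi, and 0.0282 (call gained) at 0dpa and 0.638 at 2dpa in combined RNAi against control tails. Features down with opa1 RNAi at homo had 0.151 at 6hpa in opa1 RNAi against control tails, and 0.0127 (call gained) at 1dpa in the addition of drp1 RNAi, and 0.0272 (call gained) at 1dpa and 0.114 at 2dpa in combined RNAi against control tails. Tail features up with opa1 RNAi at 2dpa had 0.0526 at 1dpa in whole-body opa1 against drp1 RNAi. Features down with sod2 RNAi at homo had 0.13 at 6hpa, 0.193 at 1dpa and 0.916 (direction turned) at 2dpa in opa1 RNAi against control tails, and 0.793 (direction turned) at 1dpa and 0.00733 (direction turned) at 2dpa in the addition of drp1 RNAi. Features up with opa1 RNAi at 1dpa had 0.0844 at 0dpa and 0.276 at 6hpa in opa1 RNAi against control tails, and 0.000174 (call gained) at 0dpa and 0.206 (direction turned) at 6hpa in the addition of drp1 RNAi.

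With adjusted p under 0.01 in both comparisons, these overlaps, among others, shrank by over 1.5 times. In the whole body at homo, 2284 features were shared by opa1 and drp1 RNAi, 104 by opa1 and sod2 RNAi and 72 by drp1 and sod2 RNAi. At 1dpa these overlaps were 276, 37 and 27. Between homo and 1dpa, 192 features were shared for opa1, 453 for drp1 and 27 for sod2 RNAi. In tails, the features that moved one way with opa1 RNAi and the other way when drp1 RNAi was added numbered 8, 21, 17 and 23 from 0dpa to 2dpa. Whole-body opa1 RNAi at homo shared 20, 24, 32 and 49 features with opa1 RNAi tails over the same times, and control whole bodies shared 671, 375 and 658 with control tails at 6hpa, 1dpa and 2dpa.

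Leaving out 1 library at a time moved these counts by over 1.5 times, each given as its range over the libraries left out and its value without each library that did so. At 0dpa, opa1 RNAi against control tails gave 22 to 61, including 30 and 22 without control replicates 1 and 2, 31 without opa1 RNAi replicate 2. At 6hpa, opa1 RNAi against control tails gave 127 to 727, including 127 and 727 without control replicates 1 and 2. At 1dpa, opa1 RNAi against control tails gave 40 to 390, including 40 and 54 without control replicates 1 and 2, 54, 390 and 69 without opa1 RNAi replicates 1, 2 and 3. At 2dpa, opa1 RNAi against control tails gave 85 to 166, including 107 and 91 without control replicates 1 and 2, 102 and 85 without opa1 RNAi replicates 1 and 2. At 0dpa, the addition of drp1 RNAi gave 36 to 314, including 314 and 36 without opa1 RNAi replicates 1 and 2, 39 and 41 without combined RNAi replicates 2 and 3. At 6hpa, the addition of drp1 RNAi gave 309 to 1610, including 357 and 1610 without opa1 RNAi replicates 1 and 2, 309 without combined RNAi replicate 2. At 1dpa, the addition of drp1 RNAi gave 29 to 145, including 31 and 145 without opa1 RNAi replicates 1 and 2, 29 and 32 without combined RNAi replicates 1 and 2. At 2dpa, the addition of drp1 RNAi gave 64 to 147, including 82 and 64 without opa1 RNAi replicates 1 and 2, 64 and 67 without combined RNAi replicates 1 and 3. At 0dpa, combined RNAi against control tails gave 13 to 197, including 13 and 197 without control replicates 1 and 3, 136, 20 and 31 without combined RNAi replicates 1, 2 and 3. At 6hpa, combined RNAi against control tails gave 49 to 222, including 196 and 75 without control replicates 1 and 3, 49 and 222 without combined RNAi replicates 2 and 3. At 1dpa, combined RNAi against control tails gave 17 to 57, including 17 and 23 without control replicates 1 and 2, 24 and 19 without combined RNAi replicates 1 and 2. At 2dpa, combined RNAi against control tails gave 43 to 56, including 43, 51 and 43 without control replicates 1, 2 and 3, 43 and 45 without combined RNAi replicates 1 and 3. At 1dpa, control tails against 0dpa gave 1378 to 2753, including 1378 without control 0dpa replicate 1, 1428 without control 1dpa replicate 3. At 2dpa, control tails against 0dpa gave 2264 to 3604, including 2264 without control 2dpa replicate 2. At 6hpa, the change of the tail opa1 RNAi effect from 0dpa gave 0 to 32, including 1 without control 0dpa replicate 1, 2 without opa1 RNAi 0dpa replicate 1, 32 and 1 without control 6hpa replicates 2 and 3, 11 and 1 without opa1 RNAi 6hpa replicates 1 and 2. At 1dpa, the change of the tail opa1 RNAi effect from 0dpa gave 0 to 13, including 1 and 1 without control 0dpa replicates 1 and 2, 6, 0 and 1 without opa1 RNAi 0dpa replicates 1, 2 and 3, 0, 1 and 1 without control 1dpa replicates 1, 2 and 3, 13 and 5 without opa1 RNAi 1dpa replicates 2 and 3. At 2dpa, the change of the tail opa1 RNAi effect from 0dpa gave 5 to 17, including 17 without opa1 RNAi 0dpa replicate 1, 5 without control 2dpa replicate 1. For opa1 at homo, whole-body RNAi against control gave 5128 to 8184, including 5128 without control replicate 3. For drp1 at homo, whole-body RNAi against control gave 3135 to 5934, including 3135 without control replicate 3. For sod2 at homo, whole-body RNAi against control gave 304 to 686, including 553 without control replicate 3, 340, 350 and 304 without sod2 RNAi replicates 1, 2 and 3. For opa1 at 1dpa, whole-body RNAi against control gave 1503 to 2235, including 1586 and 1698 without control replicates 1 and 3, 1503 without opa1 RNAi replicate 1. For drp1 at 1dpa, whole-body RNAi against control gave 894 to 2125, including 970 without control replicate 2, 894 without drp1 RNAi replicate 3. For sod2 at 1dpa, whole-body RNAi against control gave 49 to 79, including 49 without control replicate 1. At homo, whole-body opa1 against drp1 RNAi gave 478 to 1024, including 542, 478 and 586 without drp1 RNAi replicates 1, 2 and 3, 514 without opa1 RNAi replicate 1. At 1dpa, whole-body opa1 against drp1 RNAi gave 1967 to 3793, including 1967 and 2190 without drp1 RNAi replicates 1 and 3, 2154 and 2159 without opa1 RNAi replicates 1 and 2. For drp1, the whole-body change of effect from homo to 1dpa gave 366 to 1440, including 1440 and 366 without control homo replicates 1 and 3, 398 without drp1 RNAi homo replicate 1, 523 and 524 without control 1dpa replicates 1 and 3, 424 without drp1 RNAi 1dpa replicate 2. For sod2, the whole-body change of effect from homo to 1dpa gave 9 to 76, including 53 and 76 without control homo replicates 2 and 3, 13, 16 and 13 without sod2 RNAi homo replicates 1, 2 and 3, 12 without control 1dpa replicate 1, 9, 21 and 21 without sod2 RNAi 1dpa replicates 1, 2 and 3. The counts of control tails at 6hpa, control whole bodies and the whole-body opa1 change of effect stayed within 1.5 times.

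The replicate numbers of the labels were checked for pairing and do not pair the libraries. Libraries with the same number had a mean correlation of deviations of 0.00088 over 66 pairs of tail groups and 0.00725 over 28 pairs of whole-body groups. In 0 pairs were all correlations over 0.1, and libraries were closest to their own number in 66 of 198 and 34 of 84 comparisons. With the replicate number as a block, edgeR called 8036, 5633 and 960 features for opa1, drp1 and sod2 RNAi at homo and 2676, 1731 and 90 at 1dpa. The block moved no count by over 1.5 times and changed none of the set calls reported, though among all set tests it changed 1 call in tails and 5 in whole bodies.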

Other observations

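The hypotheses on dsRNA targets and the tests for control tails at 6hpa were chosen after the results were seen, as were the features named in this part, while the scaling test for SMED30032887 was fixed before. SMED30007457 was higher with each RNAi of whole bodies. At homo it stood at 171 ± 6.07 CPM in controls, 542 ± 76.3 with opa1, 350 ± 31.6 with drp1 and 233 ± 4.03 with sod2 RNAi (SD, n = 3; edgeR, highest adjusted p = 0.00216). At 1dpa these levels were 131 ± 5.27, 367 ± 11.3, 309 ± 24.6 and 240 ± 18.2 CPM (SD, n = 3; edgeR, highest adjusted p = 1.88e-08). In tails opa1 RNAi raised it by 0.72, 0.81, 1.5 and 1.49 in log2 from 0dpa to 2dpa (limma, highest adjusted p = 4.45e-05). Adding drp1 RNAi changed it by -0.39, -0.74, -0.996 and -0.95 (limma, adjusted p = 0.0532, 4.55e-05, 8.22e-08 and 1.18e-07), where 0dpa did not pass.

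SMED30012212 was lower with sod2 RNAi, at 75.6 ± 12.1 against 206 ± 29.4 CPM at homo and 37.1 ± 1.42 against 279 ± 22.5 CPM at 1dpa (SD, n = 3), and opa1 RNAi lowered it in tails at each time, by log2 fold changes of -1.38, -1.40, -2.05 and -2.24 (limma, highest adjusted p = 4.59e-07). SMED30010375, SMED30026531 and SMED30034623 fell with sod2 RNAi by -1.33, -1.50 and -2.01 in log2 at homo and by -2.28, -2.72 and -3.25 at 1dpa. In tails the effect of opa1 RNAi on these 3 was lower at 2dpa than at 0dpa, by -1.40, -1.39 and -1.29 in log2 (limma, adjusted p = 0.00165 each). SMED30015328, which fell after amputation in control tails, was lower with opa1 RNAi in whole bodies by -1.43 at homo and -1.21 at 1dpa (edgeR, adjusted p = 7.26e-09 and 4.1e-07), and with drp1 RNAi had 0.13 and 0.19 (edgeR, adjusted p = 0.498 and 0.478). The 22 features lowered over 2-fold by opa1 RNAi in tails at 1dpa had medians of -0.33 and -0.36 with sod2 RNAi at homo and 1dpa in whole bodies (camera, adjusted p = 7.32e-11 and 1.24e-24).

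SMED30032887 was lower in opa1 RNAi tails than in control tails. If the authors' scaling were the cause, the next most abundant features would have fallen alike. The next 100 had median log2 fold changes of 0.00176 to 0.143 over the 4 times. The feature fell relative to these, but centring by the scaling could give such medians, so scaling is not decided. An effect of opa1 RNAi stays open as a hypothesis, as does library preparation, which was not tested.

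More features were called in control tails at 6hpa than at later times. As causes, the largest feature's share, 25.1% at 6hpa, and the authors' scaling each predicted a large fall of the count. Without that feature and with equal totals limma called 9751, and 8711 with TMM rescaling, against 8938 as scaled by the authors, so neither accounts for it. An early response to amputation stays open, as do an unlabelled batch and lower detection (22365 to 25175 features, against 25526 to 26680 at 0dpa).

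Features that fell wherever one dsRNA was present lead to a pair of hypotheses, that the feature is the transcript the drp1 dsRNA targets, or that the feature is the transcript the opa1 dsRNA targets. Such a transcript may fall with its own dsRNA and not with the others. For drp1, 3 features fell over 2-fold in all 8 comparisons of combined RNAi with opa1 RNAi or control tails, SMED30006900, SMED30026537 and SMED30027152, and 1 of them, SMED30027152, met this in whole bodies, where drp1 RNAi lowered it 16.2-fold and 14.8-fold. For opa1, 1 feature was chosen in tails by the same measure, SMED30010319, and 0 met it in whole bodies, since drp1 RNAi at homo also lowered it, by -0.43 in log2 (edgeR, adjusted p = 0.00376, with no other tool used for this test). That change is smaller than the 8.27-fold fall with opa1 RNAi there and does not exclude a target. Both hypotheses stay open until the IDs are matched to names.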
